A study of Mus musculus with 14 samples.

How the data were processed

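RNA was measured in livers of C57BL/6 mice with a floxed Cul3 gene, which encodes the scaffold of cullin 3 RING ubiquitin ligases. Mice received a control diet (CD) or a Western diet (WD) for 13 weeks, then an adeno-associated virus (AAV), and stayed on the diet for 5 more weeks. The virus carried Cre recombinase behind the hepatocyte-specific TBG promoter (KO) or no Cre (WT). The 14 libraries fall into 4 groups by their labels: WT on CD (3 libraries), KO on CD (3), WT on WD (4) and KO on WD (4). Per the labels' protocols, total RNA was extracted with Trizol and made into stranded QuantSeq 3' FWD libraries, which read tags near the 3' end of polyadenylated transcripts, and the libraries were pooled for a NovaSeq run. Nothing in the labels ties each library to a separate animal, so the p-values measure the spread between these libraries, which may be technical.

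The authors deposited 1 table of FPKM values (fragments scaled by transcript length and by the fragments mapped in the library) for 43548 genes by 14 libraries. Cufflinks and the mm10 build are named in the submitters' processing notes, without versions. The aligner, the annotation release and the handling of reads that map to several genes are not given in the sources used here. Scaling a 3' tag count by transcript length divides genes by a length that the tag does not depend on, so FPKM levels are compared between libraries for a gene and not between genes. Total counts per library are not given in the sources used here. The most frequent value among genes with 1 transcript and under 1 FPKM, after scaling by length, would correspond to 3593000 to 11045000 reads per library if it is that of 1 read. It held 13.0 to 18.1% of those genes, so this is a rough size and gives no interval. FPKM sums ran from 443818 to 523079 per library. Gene Yam1 held the placeholder 999999999 in 8 libraries and was left out. An exact 0 can be a failed estimate, so such genes are said to be listed at 0. No 2 libraries were copies: the highest correlation of log2 values between 2 libraries was 0.958.

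From these values, log2(FPKM + 1) was tested with limma 3.58.1 in R 4.3.3 (eBayes with an intensity trend, 10 residual degrees of freedom). All 14 libraries entered 1 fit with 1 mean per group. Genes with at least 1 FPKM in at least 3 libraries were tested (10870 genes), and calls are at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Every adjusted p of a gene comes from limma. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low FPKM. The comparisons were KO against WT on each diet, WD against CD in each genotype, and the difference of the KO effect between diets. Gene lists (36, of which 33 had at least 5 tested members) were written from textbook knowledge and tested with camera (two-sided, preset correlation of 0.01), adjusted over the lists of a comparison. Camera compares a list with the other tested genes, so a list whose median is near 0 can be called down where the other genes stand higher. Of 835 list members, 828 were matched to the table, 8 of them through the GENCODE M21 annotation of mm10. The design, the lists, the first group of alternatives below and the rule for naming genes were fixed before the data were examined. Which lists to describe was chosen after their tests were seen. Named genes were Cul3, then per comparison the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 FPKM whose groups did not overlap (5 and 5 without the overlap condition for the difference), leaving out unnamed gene models, and up to 4 members with the smallest p of each list described. Some genes that this rule takes are not reported here. With 3 libraries against 3, chance leaves 10% of genes without overlap.

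The labels give no batch. Each pair of libraries was compared by the share of sparse genes (above 0 in at most 8 libraries) whose FPKM ratio falls in 1 narrow window (0.004 on the log2 scale), since genes with a single read in both libraries share 1 ratio. Average-linkage clustering of these shares into 2 gave set 1 (8 libraries: WT on CD 1, 3 and 4; WT on WD 3 and 4; KO on WD 1, 2 and 4) and set 2 (6 libraries: KO on CD 1, 2 and 3; WT on WD 1 and 2; KO on WD 3). The median sharing was 7.08% within set 1, 4.78% within set 2 and 2.63% between sets, with single pairs overlapping (2.02 to 18.1% within set 2 against 1.40 to 3.82% between sets). In the scaling by length above, the number of bases taken off the transcript length was chosen per library. It was 220 to 270 in set 1 and 190 to 240 in set 2. Whether this offset accounts for the sets was not tested. What the sets stand for is not given in the sources used here. The placeholder of Yam1 followed the sets in all libraries but KO on WD replicates 3 and 4. Replicate 3, of set 2, held it as the set 1 libraries did. Replicate 4, of set 1, measured 68780 FPKM, as the set 2 libraries had values in place of it. By this mark the set of these replicates is uncertain. On CD the sets coincide with genotype, so a set term there rests on the WD libraries.

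Alternatives fixed in advance were quantile normalization, no filter, a filter of at least 5 FPKM in at least 7 libraries, a pseudocount of 0.1, the replicate number as a block, a fit of only the groups compared, an adjusted p under 0.01, camera with an estimated correlation, fry, and leaving out each library. Alternatives chosen after seeing the data were the library set as a term (9 residual degrees of freedom), that term with quantile normalization, median centring, and the libraries of 1 set alone. Tests for counts did not apply. The fits were tested on simulated data with 200 changed genes: for KO against WT on WD and no set effect, the group fit recovered 48.8% of changes of log2 size 1 and 83.2% of size 2 among 10360 genes. With the set effect as estimated it recovered 31.8% and 78.2% (10320 genes), and for KO against WT on CD the fit with the set as a term recovered 9.4% and 55%. With the set effect as estimated, the group fit of KO against WT on CD gave on average 73.6 false calls among 174, and 4.2 among 68.6 with the set as a term (10320 genes). Without a set effect the group fit gave 10 false calls among 124.4 (10360 genes), and with the set effect but 0 changed genes it gave 1.8. The simulation drew independent normal noise per gene, without a diet effect. The number of false calls moved with the number of changed genes, so these counts do not carry over to the calls in the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.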

Results

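Liver RNA was profiled in WT mice and in mice with hepatocyte deletion of Cul3, on a control or a Western diet, to see how loss of the ligase scaffold alters the liver transcriptome under each diet. Cul3 encodes cullin 3, which with the adaptor KEAP1 marks the transcription factor NRF2 for degradation. Between 8600 and 9970 genes reached 1 FPKM per library, and the 20 genes with the highest FPKM held 30.1 to 44.7% of the summed FPKM. Since FPKM here depends on transcript length, this is not a share of reads or of RNA.

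Cul3 (ENSMUSG00000004364, mm10 chromosome 1, 80264923 to 80340480, minus strand) was first examined in every library. On CD it measured 23.9, 29.5 and 25.7 FPKM in WT and 18.3, 15.4 and 11.3 in KO. On WD it measured 12.3, 7.46, 25.9 and 18.0 FPKM in WT and 24.3, 26.6, 18.5 and 24.3 in KO. Its log2 fold change was -0.80 on CD (limma adjusted p = 0.117) and 0.65 on WD (adjusted p = 0.199), and with the library set as a term the CD value was 0.01 (adjusted p = 0.997). The deleted exons are not given in the sources used here and a 3' tag can lie outside them, so these values check neither the deletion nor the labels.

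The libraries also split along the library sets, whose meaning is not known. The first principal component (30.1% of the variance) separated the libraries of set 1 (19.3 to 39.5) from those of set 2 (-64.0 to -18.2), the second (19.0%) followed genotype, and the third (9.8%) followed diet. Between the sets 758 genes differed, 120 higher and 638 lower in set 2. All WT libraries on CD belong to set 1 and all KO libraries on CD to set 2, so on CD set and genotype cannot be told apart within the diet; values with the set as a term are given beside each comparison.

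**Figure D1:**
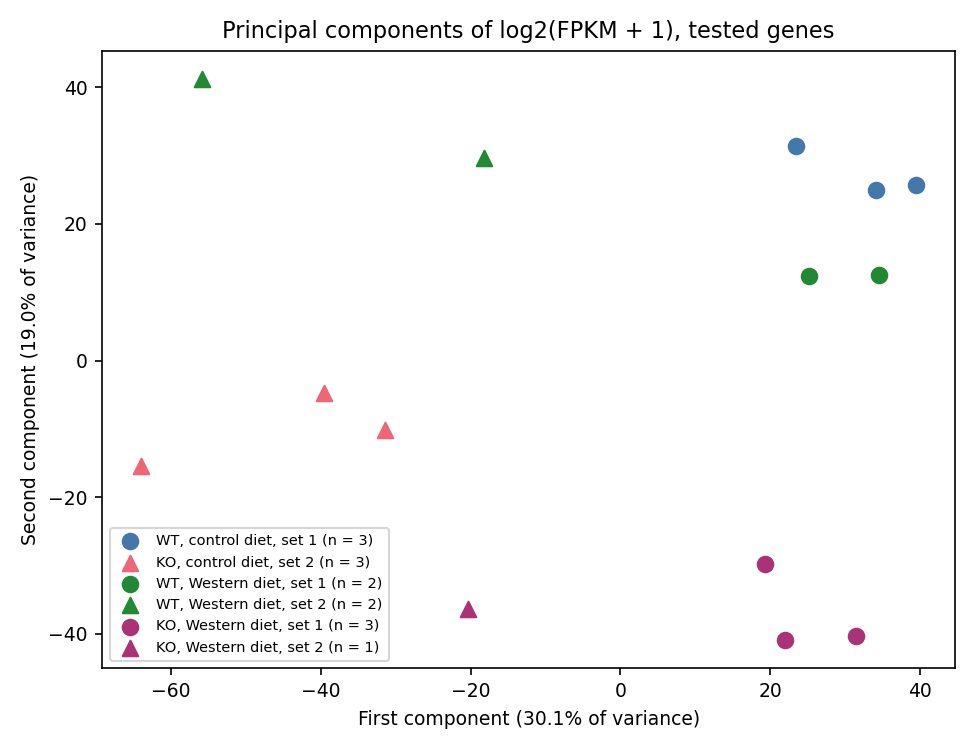
First against second principal component of log2(FPKM + 1) over the tested genes, 1 point per library, coloured by group, circles for set 1 and triangles for set 2. Set 1 libraries sit above 19 on the first axis and set 2 libraries below -18.

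In KO on CD, 16 of 30 tested NRF2 target genes and 13 of 23 interferon response genes rose, and 16 of 21 male-biased liver genes fell (8, 6 and 10 with the library set as a term). Camera called the 3 lists, and each call was lost with an estimated correlation (adjusted p = 0.177, 0.127 and 0.127 with an estimated correlation). Gstm1, a glutathione S-transferase, went from 1954 ± 371 to 31040 ± 3972 FPKM (SD, n = 3 and 3). Its log2 fold change was 4.0 ± 0.22 SE (limma adjusted p = 8.71e-07). Hsd3b5, a steroid dehydrogenase, went from 32.5 ± 12.3 to the listed values of 0, 0.265 and 0 FPKM and fell by 4.89 on the log2 scale (adjusted p = 8.30e-06). In total 1633 genes passed, 1269 up and 364 down. With the library set as a term 126 passed, 102 up and 24 down, of which 120 were among the 1633. Quantile normalization gave 1124 calls (970 of them among the 1633) and moved the share of rises from 77.7 to 54.98%, and the median gene stood 0.18 higher on the log2 scale in KO. Without 1 library the count was 894 (WT on CD replicate 1), 678 (WT on CD replicate 3), 815 (WT on CD replicate 4), 993 (KO on CD replicate 1), 591 (KO on CD replicate 3) and 2466 (WT on WD replicate 2).

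The largest rises on CD were led by Gstm3, another glutathione S-transferase (96.0 ± 14.8 to 5086 ± 614 FPKM, log2 fold change 5.72), and included the alpha-class transferase Gsta1 (4.77). Ly6d, a lipid-anchored surface protein, rose from the listed values of 0.236, 0.832 and 0 to 51.1 ± 7.41 FPKM. Cib3, a calcium-binding protein, rose by 4.91, the mucosal trefoil peptide Tff3 by 4.86 and the neurexin gene Nrxn2 by 4.73 on the log2 scale. All 6 kept the call with the set as a term (highest adjusted p = 0.0159, Tff3). The Gstm and Gsta genes are close paralogs, so the assignment of their reads is uncertain.

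Among the falls, Elovl3, an elongase of long-chain fatty acids, went from 18.1 ± 1.39 to 0.457 ± 0.453 FPKM (log2 fold change -3.75). The major urinary protein genes Mup1 (-5.23), Mup16 (-4.28) and Mup11 (-3.33) and the alpha-1-antitrypsin gene Serpina1e (-4.62) fell. They belong to near-identical families whose reads cannot be assigned with certainty. On CD the summed FPKM of the family changed by -2.49 for Mup and -0.22 for Serpina1 on the log2 scale. The Serpina1 sum thus did not fall as Serpina1e did. Cyp4a12a, a fatty acid hydroxylase, fell by 3.22 on the log2 scale. Pfn1, which encodes the actin-binding profilin, had 29.1 ± 7.88 FPKM in WT and the listed values of 0.867, 0.669 and 0 FPKM in KO (adjusted p = 0.0232). Rnu2-10, a U2 spliceosomal RNA gene, was listed at 0 in every KO library on CD and at 314, 127 and 191 FPKM in WT (adjusted p = 0.00550). It was also listed at 0 in replicate 2 of both genotypes on WD. Whether libraries of polyadenylated transcripts measure this RNA was not tested. With the set as a term, the calls of Mup1, Serpina1e, Pfn1 and Rnu2-10 ended (adjusted p = 0.132, 0.0646, 0.606 and 0.155, respectively at most 0.236, 0.108, 0.661 and 0.222 over their alternatives). Leaving out 1 library ended calls, at the highest adjusted p those of Pfn1 without KO on CD replicate 3 (adjusted p = 0.0848), and some of these calls also ended without WT on CD 3/4.

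Of the NRF2 targets on CD, 16 rose and 0 fell among 30 tested members (18 and 2 adjusted over the list alone, 8 and 0 over all genes with the set as a term). The NRF2 list had a median log2 fold change of 1.02 (camera adjusted p = 4.39e-04, and adjusted p = 0.177 with an estimated correlation). Gstp1 measured 61.5 ± 9.31 FPKM in WT and 36.2 ± 12.1 in KO, and Mgst3 13.5 ± 3.51 and 4.797 ± 2.89 (log2 fold changes -0.80 and -1.40, adjusted p = 0.109 and 0.194 over all genes). The rises included, besides Gstm1 and Gstm3, those of Gstm4 (2.55) and the efflux pump Abcc4 (0.339 ± 0.335 to 7.71 ± 1.55 FPKM). Of the male-biased genes, 0 rose and 16 fell among 21 tested members (0 and 16 adjusted over the list alone, 0 and 10 over all genes with the set as a term). The male-biased list had a median log2 fold change of -3.01 (camera adjusted p = 6.54e-19, and adjusted p = 0.127 with an estimated correlation). It draws on near-identical families. Their summed FPKM changed on CD by -2.49 (Mup), -3.22 (Cyp4a12), -0.22 (Serpina1) and -0.75 (Selenbp) on the log2 scale. For the interferon response, 13 rose and 0 fell among 23 tested members (16 and 0 adjusted over the list alone, 6 and 0 over all genes with the set as a term). The interferon list had a median log2 fold change of 1.44 (camera adjusted p = 6.67e-09, and adjusted p = 0.127 with an estimated correlation). Ifi44 went from 1.04 ± 0.443 to 20.4 ± 2.46 FPKM, and the interferon regulator Irf7 (3.28), Rtp4 (1.89) and Ifi27l2a (2.81) rose. Of female-biased genes on CD, 4 rose and 1 fell among 12 tested members (3 and 0 with the set as a term), with a median of 0.56. Camera did not call that list (adjusted p = 0.158, and 0.828 with an estimated correlation), although it did with the set as a term (0.00121). Camera did not call macrophage and Kupffer cell markers (2 up and 0 down among 16, 2 and 0 adjusted over the list alone, 0 and 0 with the set as a term, median 0.74, camera adjusted p = 0.0922, and adjusted p = 0.828 with an estimated correlation), although it did with the set as a term and with quantile normalization (adjusted p = 0.0405 and 0.0491).

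For bile acid and sterol transport on CD, 9 rose and 1 fell among 15 tested members (9 and 1 adjusted over the list alone, 3 and 0 over all genes with the set as a term). The transport list had a median log2 fold change of 1.01 (camera adjusted p = 0.00246, and adjusted p = 0.127 with an estimated correlation). The sterol transporter subunits Abcg5 (1.67) and Abcg8 (1.501) rose, as did the efflux pump Abcc3 (1.44). For fatty acid synthesis, 1 rose and 5 fell among 18 tested members (2 and 5 adjusted over the list alone, 0 and 0 over all genes with the set as a term). The fatty acid list had a median log2 fold change of -0.39 (camera adjusted p = 0.00794, and adjusted p = 0.721 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, went from 513 ± 129.8 to 104 ± 82.0 FPKM, and liver pyruvate kinase Pklr fell by 1.41 on the log2 scale. Insig2, a retention factor of the sterol sensor, rose by 1.31. In the fit with the set as a term, the calls of Abcc3, Scd1, Insig2 and Pklr ended (adjusted p = 0.0517, 0.110, 0.349 and 0.344, respectively at most 0.160, 0.136, 0.715 and 0.394 over their alternatives). Omitting 1 library ended calls, at the highest adjusted p those of Insig2 without WT on CD replicate 4 (adjusted p = 0.0572) and Pklr without WT on CD replicate 1 (adjusted p = 0.0687), and some of these calls also ended without KO on CD 1/3. All 5 lists kept the camera call with the set as a term.

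On WD, where both genotypes hold libraries of both sets, 20 of 30 tested NRF2 target genes and 17 of 23 interferon response genes rose in KO, and 13 of 21 male-biased genes fell (19, 17 and 14 with the set as a term). The 3 lists were called by camera and held with an estimated correlation (adjusted p = 0.00318, 0.0159 and 0.0159 with an estimated correlation). Gstm1 went from 2100 ± 486 to 22110 ± 3040 FPKM (SD, n = 4 and 4), a log2 fold change of 3.42 ± 0.19 SE (limma adjusted p = 1.05e-06). Elovl3 went from 15.2 ± 1.52 to 0.613 ± 0.517 FPKM (-3.37 ± 0.23 SE, adjusted p = 2.26e-06). In total 762 genes passed, 653 up and 109 down. In the fit with the set as a term 842 passed, 688 of the 762 among them. Set 1 alone (2 WT and 3 KO libraries) gave 334. Set 2 alone gave 15, with 2 WT libraries against 1 KO library, which is assumed to vary like the others. Quantile normalization moved the share of rises from 85.7 to 52.7%, with 520 calls, and median centring moved it to 49.7%, with 457. The median gene stood 0.23 higher on the log2 scale in KO. Leaving out single libraries gave counts of 454 (WT on WD replicate 1), 483 (KO on WD replicate 2) and 442 (KO on WD replicate 4).

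The largest rises on WD were Gstm3 (5.99), Gsta2 (21.8 ± 17.3 to 985 ± 281 FPKM), Gsta1 (5.45), the trypsin inhibitor Spink3 (5.47), Tff3 (4.56) and Nrxn2 (4.38). The largest falls were Hsd3b5 (20.5 ± 9.10 to 0.846 ± 0.652 FPKM), Serpina1e (-3.93) and the urinary protein genes Mup17 (-3.95), Mup16 (-3.84), Mup9 (-3.75) and Mup15 (-3.48), again of uncertain read assignment. All 12 passed with the set as a term (highest adjusted p = 0.00855, Serpina1e).

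Among NRF2 targets on WD, 20 rose and 0 fell among 30 tested members (22 and 0 adjusted over the list alone, 19 and 0 over all genes with the set as a term). The NRF2 list had a median log2 fold change of 1.49 (camera adjusted p = 8.90e-20, and adjusted p = 0.00318 with an estimated correlation). Gstm4 rose by 2.83 and Abcc4 by 2.79. Of male-biased genes, 0 rose and 13 fell among 21 tested members (0 and 16 adjusted over the list alone, 0 and 14 over all genes with the set as a term). The male-biased list had a median log2 fold change of -2.20 (camera adjusted p = 2.04e-27, and adjusted p = 0.0159 with an estimated correlation). Cyp4a12a fell by 2.89 and Mup11 fell by 3.40 on the log2 scale. In the interferon list, 17 rose and 0 fell among 23 tested members (22 and 0 adjusted over the list alone, 17 and 0 over all genes with the set as a term). The interferon list had a median log2 fold change of 1.26 (camera adjusted p = 1.73e-16, and adjusted p = 0.0159 with an estimated correlation). Ifi44 rose by 2.85, Isg15, a ubiquitin-like modifier, by 2.20, Irf7 by 1.96 and Rtp4 by 1.86. Over all 5 comparisons, the calls of these 3 lists on WD were those that held with an estimated correlation in the fit on groups alone. With the set as a term, male-biased genes in KO on CD also passed with an estimated correlation (camera adjusted p = 0.0493).

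Female-biased genes moved the other way on WD, where 6 rose and 0 fell among 12 tested members (7 and 0 adjusted over the list alone, 6 and 0 over all genes with the set as a term). The female-biased list had a median log2 fold change of 1.07 (camera adjusted p = 0.00211, and adjusted p = 0.309 with an estimated correlation). Cyp2a4 went from 0.894 ± 0.764 to 10.8 ± 3.19 FPKM, and Cyp2c69 (1.39), the fatty acid hydroxylase Cyp4a14 (2.60) and Cyp2c40 (1.0) rose, all from families of close paralogs. Of cell cycle genes, 9 rose and 0 fell among 21 tested members (12 and 0 adjusted over the list alone, 9 and 0 over all genes with the set as a term). The cell cycle list had a median log2 fold change of 0.82 (camera adjusted p = 3.32e-05, and adjusted p = 0.0555 with an estimated correlation). The mitotic kinase Cdk1 went from 2.03 ± 0.467 to 7.65 ± 0.350 FPKM, and topoisomerase Top2a (1.79) and the cyclins Ccnb2 (1.23) and Ccna2 (1.37) rose. Of macrophage and Kupffer cell markers, 5 rose and 0 fell among 16 tested members (8 and 0 adjusted over the list alone, 4 and 0 over all genes with the set as a term). The macrophage list had a median log2 fold change of 1.03 (camera adjusted p = 1.73e-04, and adjusted p = 0.309 with an estimated correlation). The Kupffer cell lectin Clec4f (1.25), complement C1qc (1.35), Vsig4 (1.10) and the monocyte antigen Ly6c2 (1.39) rose. In the same comparison camera called down hepatocyte markers (0 up and 2 down among 22, 0 and 2 adjusted over the list alone, 1 and 2 with the set as a term, median 0.01, camera adjusted p = 0.00281, and adjusted p = 0.309 with an estimated correlation), whose mean of -0.10 and median differ in sign. The call of the hepatocyte markers was also lost with fry, quantile normalization and within set 1 (adjusted p = 0.409, 0.432 and 0.175). Camera also called down pericentral hepatocyte genes (1 up and 5 down among 18, 2 and 7 adjusted over the list alone, 1 and 5 with the set as a term, median -0.13, camera adjusted p = 1.31e-04, and adjusted p = 0.1498 with an estimated correlation). Leaving 1 library out ended calls, at the highest adjusted p those of Cyp2c40 and Ly6c2 without KO on WD replicate 4 (adjusted p = 0.0603 and 0.0625) and Vsig4 without KO on WD replicate 3 (adjusted p = 0.0582), and some of these calls also ended without KO on WD 1/2 and WT on WD 4. The same 3 genes also missed the threshold under quantile normalization (adjusted p = 0.0763, 0.0865 and 0.0791, at most 0.476, 0.433 and 0.393 over their alternatives).

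For fatty acid synthesis on WD, 0 rose and 3 fell among 18 tested members (0 and 5 adjusted over the list alone, 0 and 3 over all genes with the set as a term). The fatty acid list had a median log2 fold change of -0.36 (camera adjusted p = 1.72e-06, and adjusted p = 0.1498 with an estimated correlation). Elovl5 went from 9.77 ± 3.01 to 3.01 ± 0.724 FPKM and Scd1 from 2704 ± 979 to 753 ± 215 FPKM, while Pklr fell by 1.17 on the log2 scale. Dgat2, which makes triglycerides, measured 46.3 ± 8.47 and 33.1 ± 4.25 FPKM and missed the threshold (adjusted p = 0.0903). Omission of 1 library ended calls, at the highest adjusted p those of Scd1 without WT on WD replicate 1 (adjusted p = 0.0639) and Pklr without KO on WD replicate 4 (adjusted p = 0.105), and some of these calls also ended without KO on WD 1/2/3 and WT on WD 3/4.

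**Figure D2:**
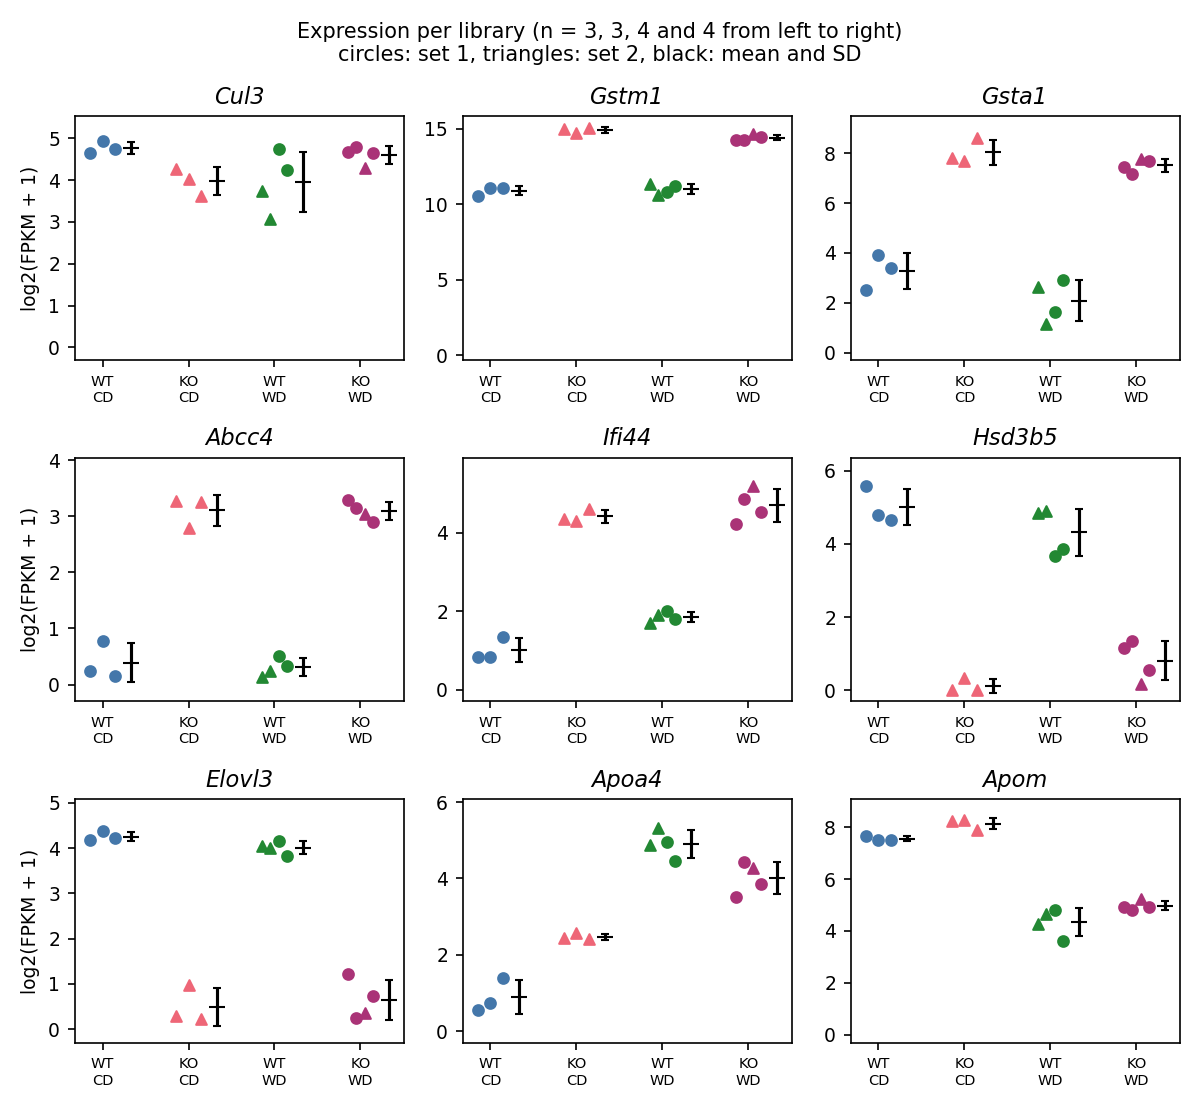
log2(FPKM + 1) of 9 genes per library in the 4 groups (3, 3, 4 and 4 libraries, circles for set 1 and triangles for set 2), with the mean and SD beside the points. Gstm1, Gsta1, Abcc4 and Ifi44 are higher and Hsd3b5 and Elovl3 lower in KO on both diets, and Cul3 overlaps between genotypes on WD.

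The KO calls on the 2 diets, which share no library, overlapped in 262 rises (76.2 expected from independent lists) and 40 falls (3.65 expected). By Fisher's exact test across genes, which are not independent replicates, p = 5.03e-84 and 1.53e-31. Both lists come from 1 fit with a shared variance per gene, so they are not independent either. With only the groups compared, 181 rises (52.0 expected) and 36 falls (5.90 expected) were shared. With the set as a term, 77 rises (6.85 expected) and 21 falls (0.247 expected) were shared. The Pearson correlation of log2 fold changes across genes was 0.07, and 0.33 with the set as a term.

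With Western diet in WT mice, 6 of 23 tested genes of cholesterol synthesis and uptake fell and 3 of 16 lipid droplet genes rose (4 and 2 with the set as a term). Camera called both lists, and both calls were lost with an estimated correlation (adjusted p = 0.0825 and 0.132 with an estimated correlation). Msmo1, an oxidase of sterol synthesis, went from 108 ± 5.94 to 16.0 ± 1.40 FPKM (SD, n = 3 and 4), a log2 fold change of -2.67 ± 0.33 SE (limma adjusted p = 0.00142). Cidec, a lipid droplet protein, went from the listed values of 0, 0.480 and 1.90 to 19.5 ± 7.28 FPKM (3.58 ± 0.55 SE, adjusted p = 0.00555). In total 141 genes passed, 72 up and 69 down. In the set term fit 76 passed, 34 up and 42 down, 65 of them among the 141, and set 1 alone gave 46. Median centring moved the share of rises from 51.1 to 40.9%. Counts moved on leaving out 1 library, to 65 (WT on CD replicate 1), 40 (WT on CD replicate 3), 44 (WT on CD replicate 4) and 57 (WT on WD replicate 1).

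Other large rises in WT were Ly6d (4.27), the apolipoprotein Apoa4 (0.931 ± 0.620 to 29.6 ± 7.60 FPKM), the glypican Gpc1 (2.72), Scd1 (2.36) and the cytokine Il1b (2.29). Apom, an apolipoprotein of HDL, went from 187 ± 11.8 to 20.2 ± 7.01 FPKM. The organic anion transporter Slco1a4 fell by 2.71, the methyltransferase Gnmt fell by 2.34 and Enho, which encodes the peptide adropin, fell by 2.64 on the log2 scale. Cyp3a41a also fell (-3.21), with reads that near-identical Cyp3a genes can share. With the library set as a term, the calls of Scd1, Il1b and Cyp3a41a ended (adjusted p = 0.0685, 0.0906 and 0.0506, respectively at most 0.145, 0.133 and 0.107 over their alternatives). Leaving out single libraries ended calls, at the highest adjusted p those of Scd1, Enho and Cyp3a41a without WT on CD replicate 3 (adjusted p = 0.145, 0.123 and 0.107) and Il1b without WT on CD replicate 1 (adjusted p = 0.133), and some of these calls also ended without WT on CD 4 and WT on WD 1/2/3/4.

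In the cholesterol list in WT, 0 rose and 6 fell among 23 tested members (0 and 14 adjusted over the list alone, 0 and 4 over all genes with the set as a term). The cholesterol list had a median log2 fold change of -0.98 (camera adjusted p = 1.24e-14, and adjusted p = 0.0825 with an estimated correlation). The sterol demethylase Cyp51 (-2.29), Nsdhl (-2.33) and the isomerase Idi1 (-2.87) fell. Of cytochrome P450 genes, 0 rose and 3 fell among 29 tested members (1 and 13 adjusted over the list alone, 0 and 2 over all genes with the set as a term). The cytochrome list had a median log2 fold change of -0.54 (camera adjusted p = 3.73e-06, and adjusted p = 0.0825 with an estimated correlation). Cyp2c29 (-1.88), Cyp1a2 (-1.55) and Cyp2a5 (-1.82) fell. Cyp3a11 measured 4066 ± 962 and 549 ± 687 FPKM (adjusted p = 0.0543). For amino acid metabolism, 0 rose and 2 fell among 24 tested members (0 and 9 adjusted over the list alone, 0 and 1 over all genes with the set as a term). The amino acid list had a median log2 fold change of -0.57 (camera adjusted p = 8.73e-06, and adjusted p = 0.0825 with an estimated correlation). The urea cycle enzyme Cps1 (-1.30) and the transaminase Got1 (-1.65) fell, while Cth missed the threshold (adjusted p = 0.0902). In the fit with set as a term, the calls of Cyp2a5 and Got1 ended (adjusted p = 0.0728 and 0.0578, respectively at most 0.147 and 0.103 over their alternatives). Fits that left out 1 library ended calls, at the highest adjusted p those of Cyp1a2 without WT on CD replicate 4 (adjusted p = 0.0676) and Cyp2a5 and Got1 without WT on CD replicate 3 (adjusted p = 0.144 and 0.0852), and some of these calls also ended without WT on CD 1 and WT on WD 1/3.

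Of female-biased genes in WT, 0 rose and 3 fell among 12 tested members (0 and 6 adjusted over the list alone, 0 and 1 over all genes with the set as a term). The female-biased list had a median log2 fold change of -0.84 (camera adjusted p = 8.73e-06, and adjusted p = 0.132 with an estimated correlation). All 3 belong to the Cyp3a family, with Cyp3a41b at -2.89 and Cyp3a44 at -1.19, and Cyp2c40 missed the threshold (adjusted p = 0.119). In the lipid droplet list, 3 rose and 0 fell among 16 tested members (5 and 0 adjusted over the list alone, 2 and 0 over all genes with the set as a term). The lipid droplet list had a median log2 fold change of 0.64 (camera adjusted p = 3.18e-04, and adjusted p = 0.132 with an estimated correlation). Cidea, a lipid droplet protein, was listed at 0 in every WT library on CD and at 21.7, 5.96, 14.2 and 4.47 FPKM on WD (adjusted p = 7.60e-04). Plin4 rose by 1.01, and Plin2 missed the threshold (0.0854). For fatty acid synthesis, 3 rose and 0 fell among 18 tested members (6 and 0 adjusted over the list alone, 1 and 0 over all genes with the set as a term). The fatty acid list had a median log2 fold change of 0.42 (camera adjusted p = 0.0282, and adjusted p = 0.507 with an estimated correlation). Elovl5 rose by 1.37 and Insig2 by 1.25, with Agpat2 short of the threshold (0.0978). Once the set was a term, the calls of Cyp3a44, Plin4 and Insig2 ended (adjusted p = 0.0906, 0.157 and 0.151, respectively at most 0.168, 0.172 and 0.206 over their alternatives). Fitting without 1 library ended calls, at the highest adjusted p those of Cyp3a41b and Cyp3a44 without WT on CD replicate 3 (adjusted p = 0.0913 and 0.168) and Plin4, Elovl5 and Insig2 without WT on CD replicate 4 (adjusted p = 0.172, 0.0860 and 0.206), and some of these calls also ended without KO on CD 1/2/3, KO on WD 1/2/3/4, WT on CD 1 and WT on WD 1/2/3/4.

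With Western diet in KO mice, 8 of 23 tested genes of cholesterol synthesis and uptake and 6 of 24 genes of amino acid metabolism fell (1 and 3 with the set as a term). Camera called both lists, and both calls were lost with an estimated correlation (adjusted p = 0.149 and 0.116 with an estimated correlation). Cyp51 went from 60 ± 20.1 to 13.0 ± 3.01 FPKM (SD, n = 3 and 4), a log2 fold change of -2.09 ± 0.25 SE (limma adjusted p = 0.00143). Hpd, an enzyme of tyrosine breakdown, went from 2125 ± 96.2 to 888 ± 132 FPKM (-1.27). In total 693 genes passed, 416 up and 277 down. With the set as a term 38 passed (14 up, 24 down, 37 of them among the 693). Within set 2 (3 libraries against 1) the median log2 fold change was 0.11. The KO group on WD has 1 library there, so a count of calls within set 2 decides nothing. The share of rises moved from 60.03 to 42.0% under quantile normalization and to 32.3% under median centring. Without 1 library the count was 412 (WT on CD replicate 3), 417 (WT on CD replicate 4), 113 (KO on CD replicate 1), 324 (KO on CD replicate 2), 148 (KO on CD replicate 3), 1767 (WT on WD replicate 2), 284 (KO on WD replicate 1), 143 (KO on WD replicate 2), 1128 (KO on WD replicate 3) and 194 (KO on WD replicate 4).

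Falls in KO that kept the call with the set as a term were Slco1a4 (75.3 ± 5.61 to 7.54 ± 3.44 FPKM), Apom (-3.15), Gnmt (-2.73), the carboxylesterase Ces2a (-2.32) and Cyp3a41a (-2.40, of uncertain read assignment). Rmrp, the RNA of RNase MRP, was listed at 0 in every KO library on WD and at 11.7, 2.73 and 54.2 FPKM on CD (adjusted p = 0.0443). In WT it was also listed at 0 in replicates 1 and 3 on CD and 1 and 2 on WD. Whether libraries of polyadenylated transcripts measure this RNA was not tested. The largest rises were Pfn1 (4.15), the exon junction protein Magohb (3.97), the translation termination factor Gspt1 (3.85), the protease inhibitor Spint2 (3.65), the protease Lgmn (3.54) and Plac8 (3.45). After adding the set as a term, the calls of Rmrp, Pfn1, Magohb, Gspt1, Spint2, Lgmn and Plac8 ended (adjusted p = 0.129, 0.242, 0.0581, 0.176, 0.239, 0.141 and 0.279, respectively at most 0.634, 0.328, 0.0844, 0.578, 0.597, 0.200 and 0.682 over their alternatives). Fits without 1 library ended calls, at the highest adjusted p those of Cyp3a41a and Magohb without KO on CD replicate 1 (adjusted p = 0.112 and 0.0677) and Rmrp, Pfn1, Gspt1, Spint2, Lgmn and Plac8 without KO on CD replicate 3 (adjusted p = 0.156, 0.121, 0.117, 0.129, 0.0820 and 0.106), and some of these calls also ended without KO on CD 2, KO on WD 1/2/4, WT on CD 1/3/4 and WT on WD 1.

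In the cholesterol list in KO, 0 rose and 8 fell among 23 tested members (1 and 13 adjusted over the list alone, 0 and 1 over all genes with the set as a term). The cholesterol list had a median log2 fold change of -0.85 (camera adjusted p = 5.01e-09, and adjusted p = 0.149 with an estimated correlation). Acat2 (-1.61), Msmo1 (-2.02) and Mvd (-2.11) fell. For amino acid metabolism, 0 rose and 6 fell among 24 tested members (0 and 9 adjusted over the list alone, 0 and 3 over all genes with the set as a term). The amino acid list had a median log2 fold change of -0.44 (camera adjusted p = 1.53e-04, and adjusted p = 0.116 with an estimated correlation). Got1 (-2.01), the urea cycle enzyme Asl (-1.14) and Mat1a, which makes S-adenosylmethionine (-1.15), fell. Camera also called down hepatocyte markers (0 up and 4 down among 22, 0 and 8 adjusted over the list alone, 0 and 1 with the set as a term, median -0.51, camera adjusted p = 4.16e-05, and adjusted p = 0.198 with an estimated correlation). Of female-biased genes, 0 rose and 4 fell among 12 tested members (0 and 5 adjusted over the list alone, 0 and 3 over all genes with the set as a term). The female-biased list had a median log2 fold change of -0.68 (camera adjusted p = 0.00106, and adjusted p = 0.207 with an estimated correlation). The transcription factor Cux2 had 20.01 ± 8.56 FPKM on CD and the listed values of 0, 0.407, 1.18 and 1.98 FPKM on WD, and the steroid hydroxylase Cyp17a1 (-1.79) and Cyp3a44 (-1.07) fell. In WT, Cux2 was listed at 0, 0 and 0.018 FPKM on CD and at 0.17, 0.18, 0.036 and 0.094 FPKM on WD. Its fall in KO thus started from a level that WT reached on neither diet. When the set was a term, the calls of Acat2, Msmo1, Mvd, Mat1a and Cyp3a44 ended (adjusted p = 0.0701, 0.0560, 0.122, 0.239 and 0.179, respectively at most 0.634, 0.606, 0.647, 0.725 and 0.179 over their alternatives). Dropping 1 library ended calls, at the highest adjusted p those of Mvd, Asl and Mat1a without KO on CD replicate 3 (adjusted p = 0.0844, 0.0567 and 0.0916) and Cyp17a1 and Cyp3a44 without KO on CD replicate 1 (adjusted p = 0.0606 and 0.105), and some of these calls also ended without KO on CD 2 and KO on WD 1/2/4.

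Of cell cycle genes in KO, 7 rose and 0 fell among 21 tested members (11 and 0 adjusted over the list alone, 0 and 0 over all genes with the set as a term). The cell cycle list had a median log2 fold change of 0.76 (camera adjusted p = 1.53e-04, and adjusted p = 0.116 with an estimated correlation). Ccnb2 (1.23), Pcna, the DNA polymerase clamp (1.05), Ube2c (1.89) and Top2a (1.11) rose. For cytokines, chemokines and adhesion, 5 rose and 0 fell among 17 tested members (7 and 0 adjusted over the list alone, 0 and 0 over all genes with the set as a term). The cytokine list had a median log2 fold change of 0.74 (camera adjusted p = 0.00215, and adjusted p = 0.116 with an estimated correlation). The hyaluronan receptor Cd44 went from 1.65 ± 0.529 to 15.6 ± 6.31 FPKM, and the chemokines Cxcl10 (1.45) and Cxcl9 (1.27) rose. Both lists kept the camera call with the set as a term (adjusted p = 5.57e-05 and 9.78e-04), although in that limma fit 0 members of either passed singly. In the same comparison camera called up macrophage and Kupffer cell markers (0 up and 0 down among 16, 4 and 0 adjusted over the list alone, 0 and 0 with the set as a term, median 0.75, camera adjusted p = 0.00105, and adjusted p = 0.358 with an estimated correlation). In that fit, the calls of Ccnb2, Pcna, Ube2c, Top2a, Cd44, Cxcl10 and Cxcl9 ended (adjusted p = 0.0557, 0.226, 0.259, 0.222, 0.0756, 0.213 and 0.154, respectively at most 0.0784, 0.720, 0.366, 0.725, 0.571, 0.645 and 0.574 over their alternatives). Removal of 1 library ended calls, at the highest adjusted p those of Ccnb2 and Pcna without KO on CD replicate 3 (adjusted p = 0.0587 and 0.0891) and Ube2c, Top2a, Cxcl10 and Cxcl9 without KO on CD replicate 1 (adjusted p = 0.0897, 0.112, 0.0876 and 0.105), and some of these calls also ended without KO on CD 2 and KO on WD 1/2/4.

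**Figure D3:**
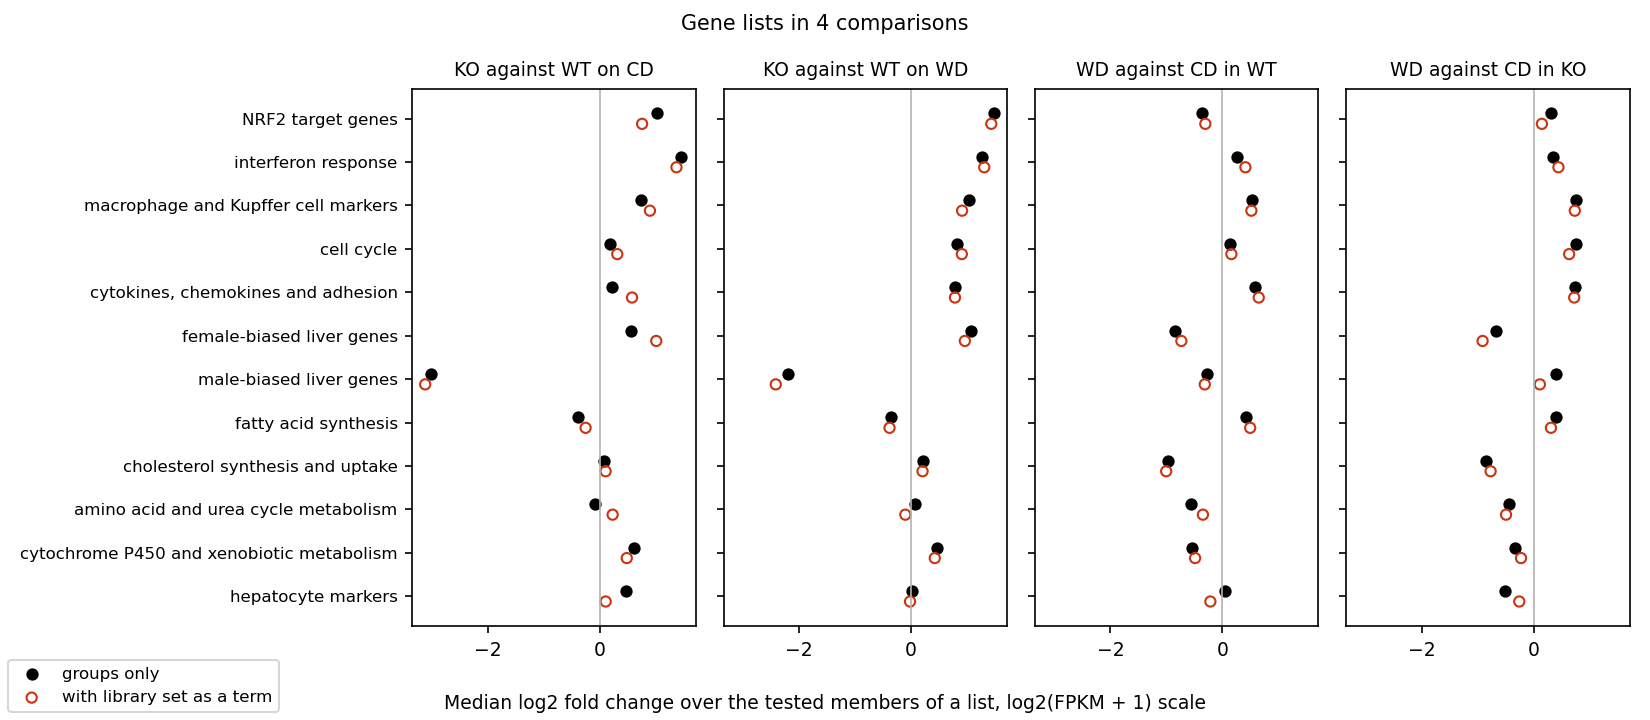
Median log2 fold change over the tested members of 12 gene lists in 4 comparisons, for the fit on groups alone (filled) and with the library set as a term (open). Male-biased genes lie at -3.01 and -2.20 in KO on CD and WD, NRF2 targets at 1.02 and 1.49, and cholesterol genes at -0.98 and -0.85 with WD in WT and KO.

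The diet calls in WT and KO, which share no library, had 11 rises in common (2.76 expected from independent lists) and 20 falls (1.76 expected). By Fisher's exact test across genes p = 8.32e-05 and 2.54e-16. Both lists come from 1 fit with a shared variance per gene, so they are not independent. With only the groups compared, 5 rises (1.64 expected, Fisher p = 0.0197) and 10 falls (0.756 expected, Fisher p = 6.91e-10) were shared. Under the stricter filter it was 8 rises (4.31 expected, Fisher p = 0.0632) and 21 falls (3.92 expected, Fisher p = 4.09e-11). When the set was a term, 1 rise and 8 falls were shared (0.0438 and 0.0927 expected). The Pearson correlation across genes was -0.21, and 0.10 with the set as a term.

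The test of whether the KO effect differed between diets called 37 genes, 24 with a more positive and 13 with a more negative KO effect on WD, and 2 with the set as a term. Manf, a factor secreted under endoplasmic reticulum stress, measured 178 ± 36.4 FPKM in WT and 44.6 ± 30.1 FPKM in KO on CD, and 87.9 ± 48.0 FPKM and 260.4 ± 69.2 FPKM on WD (SD, n = 3, 3, 4 and 4). Its coefficient was 3.91 ± 0.72 SE (limma adjusted p = 0.0384). Apoa4 measured 0.931 ± 0.620 and 4.57 ± 0.319 FPKM on CD and 29.6 ± 7.60 and 15.7 ± 4.60 on WD (-2.46, adjusted p = 0.0240). Further positive coefficients were those of Chac2, an enzyme of glutathione breakdown (3.45), the actin regulator Lrrc16a (3.12), the RNA-binding protein Rbpms (2.72) and the ketone body enzyme Oxct1 (2.29). Negative ones were those of Gpc1 (-2.45), Dhodh of pyrimidine synthesis (-2.23), the acyltransferase Agpat6 (-1.85) and the splicing factor Rbm25 (-1.67). With the set added as a term, the calls of Manf, Chac2, Lrrc16a, Rbpms, Oxct1, Apoa4, Gpc1, Dhodh, Agpat6 and Rbm25 ended (adjusted p = 0.784, 0.527, 0.784, 0.289, 0.527, 0.527, 0.746, 0.374, 0.766 and 0.790, respectively at most 0.784, 0.527, 0.784, 0.289, 0.534, 0.527, 0.746, 0.374, 0.766 and 0.790 over their alternatives). Omitting single libraries ended calls, at the highest adjusted p those of Manf, Chac2, Lrrc16a, Rbpms, Oxct1, Apoa4, Agpat6 and Rbm25 without WT on CD replicate 3 (adjusted p = 0.113, 0.0821, 0.117, 0.0821, 0.1202, 0.0821, 0.133 and 0.133) and Gpc1 without KO on CD replicate 3 (adjusted p = 0.104), and some of these calls also ended without KO on CD 1/2, KO on WD 1/2/4, WT on CD 1/4 and WT on WD 1/2. The share of positive coefficients moved from 64.9 to 52.8% under quantile normalization. On leaving out 1 library the count was 7 (WT on CD replicate 1), 4 (WT on CD replicate 3), 8 (WT on CD replicate 4), 24 (KO on CD replicate 1), 9 (KO on CD replicate 2), 12 (KO on CD replicate 3), 7 (WT on WD replicate 1), 666 (WT on WD replicate 3), 1058 (WT on WD replicate 4), 14 (KO on WD replicate 2), 759 (KO on WD replicate 3) and 15 (KO on WD replicate 4).

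Of 4 lists called for the difference, NRF2 targets (median 0.56) and cell cycle genes (0.51) were more positive on WD, and proteasome subunits (-0.48) and hepatocyte markers (-0.63) more negative, each at a camera adjusted p = 0.0278. With an estimated correlation the adjusted p = 0.633, 0.633, 0.646 and 0.816, which ended all 4 calls. With the set as a term the first 2 held (adjusted p = 0.00173 and 0.0302) and the last 2 did not (0.324 and 0.659). Under quantile normalization the list that held was that of NRF2 targets. With WD in WT the NRF2 list had a median of -0.37 and was called down (camera adjusted p = 0.00524, and adjusted p = 0.176 with an estimated correlation), and with WD in KO it had a median of 0.31 and was not called (camera adjusted p = 0.160, and 0.0291 with quantile normalization). For the difference, limma called 0 members of the 4 lists over all genes. Adjusted over the list alone, 8 NRF2 targets and 3 cell cycle genes were more positive, 8 proteasome subunits and 6 hepatocyte markers more negative, and 1 proteasome subunit and 2 hepatocyte markers more positive.

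Gclc, the catalytic subunit of an enzyme of glutathione synthesis, measured 104 ± 13.3 and 96.1 ± 15.8 FPKM in WT and KO on CD and 87.4 ± 23.1 and 248 ± 65.7 on WD (adjusted p = 0.0573). Gstp1, Mgst3 and Ugdh had coefficients of 2.16, 4.38 and 3.06 (adjusted p from 0.0548 to 0.0607). Ccnb2, Pcna, Cenpa and Ccna2 had 1.49, 1.11, 1.48 and 1.20 (0.0610 to 0.106). Of the proteasome, Psmc4, Psmc3, Psmb6 and Psma4 had -1.19, -1.30, -0.99 and -0.92 (0.0616 to 0.0798). Among hepatocyte markers, Hpd, Serpina1c, Cps1 and Tdo2 had -1.02, -1.20, 1.03 and 1.86 (0.0603 to 0.0719), in both directions. All these coefficients are from the fit on groups alone, and every KO library on CD belongs to set 2. On WD, Gstp1, Mgst3 and Ugdh were lower in the set 2 libraries of each genotype. Ugdh measured 24.4 and 17.4 FPKM there in WT, against 58.5 and 80.7 in set 1. In KO it measured 104 FPKM in set 2, against 261, 251 and 267 in set 1. The set may thus enter these coefficients.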

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

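The tests of library batch, depth and GC content for the CD calls and the counts of splits were set before their results were seen. The tests on the excess of rises, on sex, on paralogs and on hepatocyte share were chosen after the result was seen. The test on family sums was added after a first test on paralogs had left that explanation open, and both are given.

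Calls between KO and WT on CD coincide with the 2 library sets, and across tested genes the CD fold changes had a Pearson r of 0.613 with the set effect estimated from the WD libraries alone, which share no library with them, so a difference in library processing may account for part of the 1633 calls. With the set as a term, 120 of these calls still passed, while over all 1633 the median absolute log2 fold change went from 1.11 to 0.74 and the standard error rose by a median factor of 1.26. GC content is argued against as the whole of the set difference, since 79.5% of the 758 genes that differ between sets stayed past the threshold after correction for the GC content of 3' ends, while with depth as a further term 40.9% did. There the set effect kept a median 0.882 of its size (quartiles 0.779 and 0.985) and its standard error rose by a median factor of 1.10, so the lost calls do not speak for depth, which stays open because the implied reads are rough and go with the set (Pearson r -0.70). The set and the genotype cannot be told apart on CD, and the genotype effect stays open for the calls lost with the set term.

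Rises outnumbered falls in KO on WD (85.7%). Median centring gave a share of 49.7%, but it brings the share near even by construction, so it decides nothing. The 20 genes with the highest FPKM held 30.1 to 32.3% of the summed FPKM in KO on WD and 37.5 to 44.7% in WT on WD. This is not a share of reads, and whether it lifts the FPKM of the other genes stays open. With the set as a term the share was 86.7%. On WD the sets are near balance between genotypes (set 2 holds 2 WT libraries and 1 KO library), so this term could move the share little and decides little. Other differences in library processing were not tested. A true rise of RNA per cell gives the same relative values and was not tested.

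Male-biased genes fell in KO on WD (median -2.20). A difference in sex is argued against, since the lowest Ddx3y value, a Y-linked gene, was 15.7 FPKM in the KO libraries and 11.5 in WT, and Xist reached at most 0.649 FPKM. Hepatocyte markers were called down by camera (adjusted p = 0.00281, and adjusted p = 0.309 with an estimated correlation and 0.432 with quantile normalization) and macrophage markers up (1.73e-04 and 0.309). The hepatocyte marker median was 0.0134 (SD 0.44 over 22 genes), with the median tested gene at 0.23. These values argue against a lower share of hepatocytes as the whole of a fall of this size. For reads shared between paralogs, the 6 tested members outside near-identical families had a median of -0.62, with 2 past the threshold, which left it open; the summed FPKM of 4 families then changed by a median of -1.47 on the log2 scale, with Mup at -2.20 and Cyp4a12 at -2.92 but Serpina1 at -0.75 and Selenbp at 0.58. Exchange of reads within a family is thus argued against for Mup and Cyp4a12 as families and stays open for the other members, and so does an effect of the genotype, which the design names.

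Regrouping the libraries gave these counts. For KO against WT on WD, 1 of 35 splits (the real one) called as many as 762 genes, and the highest other called 100. For WD against CD in WT, 1 of 35 splits called as many as 141 (highest other 5). In both, 1 of 35 is the smallest share that the splits can give, and it was not corrected over comparisons. The other splits also mix libraries of both groups, which widens the spread and lowers their counts. These counts make chance less likely but do not exclude it. For WD against CD in KO, 1 of 35 called as many as 693, which excludes neither chance nor the library sets. The highest other, 220, parts set 2 (KO on CD 1, 2 and 3 and KO on WD 3) from set 1, the real grouping differs from it by 1 library, and with the set as a term 38 genes passed. For KO against WT on CD the 10 splits are too few for a share under 0.05 (real 1633, highest other 1). For the difference between diets, 5 of 100 drawn splits called as many as the real 37, so chance cannot be excluded. The other 4 all parted the CD libraries as the real grouping does, where set and genotype coincide. Those with 44, 101 and 139 calls did so with the KO and WT labels exchanged on CD, which tests another contrast. The highest of them kept the real labels on CD and called 1943 genes against the real 37, which points to a structure of the samples. On WD it set 4 libraries of set 1 (WT replicate 4, KO replicates 1, 2 and 4) against 3 of set 2 and WT replicate 3. With the set as a term the real grouping called 2.

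Of 205 values tested in groups of 4 libraries for a library far from the others (the gap to the nearest value over the range), 16 passed Dixon's critical value, and chance gives about 1 in 20. KO on WD replicate 3, the library of set 2 in its group, was low for Gspt1 (0.972), Spint2 (0.908), Ube2c (0.861) and Magohb (0.843) and high for Cidec (0.872). In the same group replicate 4 was low for Il1b (0.837) and replicate 2 high for Cd44 (0.837) and Cidea (1, with the other 3 listed at 0). In WT on WD, replicate 2 was high for Mat1a (0.89) and Il1rn (0.841) and low for Slco1a4 (0.874), replicate 4 low for Tff3 (0.918) and high for Cyp3a41b (0.841), replicate 3 high for Mvd (0.871) and Spink3 (1, the others listed at 0), and replicate 1 high for Acat2 (0.845).

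The interaction term in limma, fitted on groups alone, was past the threshold for Manf (3.91), Chac2 (3.45), Lrrc16a (3.12), Rbpms (2.72), Oxct1 (2.29), Apoa4 (-2.46), Gpc1 (-2.45), Dhodh (-2.23), Agpat6 (-1.85) and Rbm25 (-1.67). All 10 calls ended with the set as a term (adjusted p from 0.289 to 0.790), and chance was not excluded for this comparison.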

How the results depend on the processing

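The settings with the library set, with median centring and within 1 set, the quantile setting of the gene lists and the replicate block of the overlaps were chosen after the data were seen. The others were fixed in advance. Of 140 named results past the threshold (a gene in a comparison), 41 kept direction and call under every alternative run, 131 under quantile normalization, 126 with a pseudocount of 0.1, 111 without a filter, 133 with median centring, 89 with the library set as a term and 87 in all fits without 1 library. Under the stricter filter 113 were tested and 113 kept. With the replicate block 96 kept, with the set term and quantile normalization 87, with only the groups compared 118 of 129, and within set 1 alone 44 of 62. The 41 also had to hold in the fits within set 2, which has 1 KO library on WD. Unless a cause is named, the cause was not tested. Depth is known only roughly, which limits the calls of genes at low FPKM.

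Counts of genes with the library set as a term were 126 (KO on CD, main 1633), 76 (WD in WT, 141), 38 (WD in KO, 693) and 2 (difference, 37), and with that term and quantile normalization 84, 85, 35 and 2. Median centring gave 457 for KO on WD (main 762). Fits of only the groups compared gave 445 for KO on WD, 46 for WD in WT and 1182 for WD in KO. With fewer libraries, set 1 alone gave 334 for KO on WD and 46 for WD in WT, and set 2 alone 15 and, for WD in KO, 0. Without a filter WD in KO gave 351 and the difference 21; the stricter filter gave 220 for the difference, where fewer genes are tested, and a pseudocount of 0.1 gave 24. At an adjusted p under 0.01 and an absolute log2 fold change of at least 1, counts were 332, 244, 37, 53 and 3 in the order of comparisons, against 998, 468, 111, 457 and 37 at 0.05.

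The same replicate numbers recur in the groups, and no pairing by number was seen. The 18 same-numbered pairs had correlations of -0.297 to 0.158, 2 of them above 0.1. The best partner carried the same number in 8 of 36 cases. The library sets can enter these correlations and hide a pairing. The lowest was that of replicate 3 of WT and KO on WD, which lie in different sets. With the number as a replicate block the counts were 586 (KO on CD), 530 (KO on WD), 60 (WD in WT), 85 (WD in KO) and 4 (difference), and the overlaps 162 KO rises, 4 diet rises and 6 diet falls.

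Without 1 library the counts ran from 591 to 2466 for KO on CD (without KO on CD replicate 3 and WT on WD replicate 2), 442 to 801 for KO on WD (KO on WD replicate 4 and WT on WD replicate 3), 40 to 141 for WD in WT (WT on CD replicate 3 and KO on CD replicate 3), 113 to 1767 for WD in KO (KO on CD replicate 1 and WT on WD replicate 2) and 4 to 1058 for the difference (WT on CD replicate 3 and WT on WD replicate 4).

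With an estimated correlation 0, 3, 0, 0 and 0 lists passed in the order of comparisons (main 5, 14, 14, 13 and 4). For KO on CD fry gave 12 and the set term 8; for the difference the set term gave 7 and quantile normalization 1. The lipid droplet list of KO on WD changed direction within set 2, which holds 1 KO library on WD (adjusted p = 0.691, over alternatives 0.00291 to 0.691), as did Cidec there (log2 fold change 0.00936). Camera with both an estimated correlation and the set as a term was not among the alternatives. In KO on WD it gave higher adjusted p for NRF2 targets and cell cycle genes (0.00658 and 0.0745, against 0.00318 and 0.0555). For every list described with its members, except lipid droplet genes in KO on WD, the adjusted p with an estimated correlation is the highest over its alternatives. Besides that setting, calls ended with fry for fatty acid synthesis (KO on CD and WD in WT), within set 1 for female-biased genes (KO on WD), with quantile normalization for cell cycle genes (difference), and with the set term and quantile normalization for proteasome subunits and hepatocyte markers (difference), the latter also with fry and the replicate block. Of the marker lists given without members, hepatocyte markers (KO on WD) lost the call with fry, quantile normalization and within set 1 (adjusted p = 0.409, 0.432 and 0.175), and pericentral genes (KO on WD) and macrophage markers (WD in WT) with fry (0.0636 and 0.145).

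Shared KO rises (main 262) were 126 with quantile normalization, 115 with median centring, 77 with the set term and 43 with both the term and quantile normalization; shared KO falls (40) were 21 and 23 with the last 2. Shared diet rises (11) were 5 without a filter, 6 with median centring, 5 with only the groups compared, and 1 with the set term, with or without quantile normalization; shared diet falls (20) were 8 and 9 with the set term and 10 with only the groups compared.

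For Cul3 in KO on CD the value was 0.00617 with the set term, against -0.80; fitting only the groups compared left -0.80 and put it past the threshold, and without 1 library it ran from -0.95 to -0.62. Its coefficient for the difference ran from 1.15 to 1.71 without 1 library and passed at 1.71, without WT on WD replicate 3. Tests for counts listed in advance were not run, since the table holds no counts.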

Other observations

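The test of Cidea and Cidec below was chosen after their values were seen. Lipid droplet genes differed between KO and WT on WD in opposite directions. Cidea, a protein of lipid droplet fusion, was listed at 21.7, 5.96, 14.2 and 4.47 FPKM in WT and at 0, 0.124, 0 and 0 in KO (log2 fold change -3.38, limma adjusted p = 6.93e-05), and Plin4, a droplet coat protein, fell by 1.14 on the log2 scale (adjusted p = 0.00530), while the fatty acid transporter Cd36 rose from 23.2 ± 6.13 to 62.8 ± 9.44 FPKM (adjusted p = 0.0114). Cidec measured 19.5 ± 7.28 and 6.54 ± 5.66 FPKM and missed the threshold (adjusted p = 0.0764). Over the list 1 rose and 2 fell among 16 tested, 2 and 4 adjusted over the list alone. Its median was 0.05 and its mean -0.26, and camera called it down (adjusted p = 0.00917, and adjusted p = 0.309 with an estimated correlation). That call also ended with fry and with quantile normalization. A smaller diet response of both Cidea and Cidec in KO is a hypothesis: the difference of the diet effect passed for Cidea (adjusted p = 0.0241) but not for Cidec (0.140), and Cidea lost it with the set as a term (0.527), so the tables leave it open.

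For stellate cell and matrix genes with WD in KO, 4 rose and 0 fell among 15 tested members (4 and 0 adjusted over the list alone, 0 and 0 over all genes with the set as a term). The stellate list had a median log2 fold change of 0.42 (camera adjusted p = 0.0238, and adjusted p = 0.207 with an estimated correlation). The collagens Col1a2 (2.60 ± 0.305 to 7.69 ± 0.987 FPKM) and Col3a1 (1.63), fibronectin Fn1 (2.05) and Lrat, which stores retinol as esters (1.14), rose. Adding the set as a term, the calls of Col1a2, Col3a1, Fn1 and Lrat ended (adjusted p = 0.136, 0.343, 0.242 and 0.234, respectively at most 0.574, 0.667, 0.642 and 0.684 over their alternatives). Leaving 1 library out ended calls, at the highest adjusted p those of Col1a2 and Col3a1 without KO on CD replicate 1 (adjusted p = 0.0523 and 0.114) and Fn1 and Lrat without KO on CD replicate 3 (adjusted p = 0.104 and 0.0775), and some of these calls also ended without KO on CD 2 and KO on WD 1/2/4. With WD in KO, camera also called hepatocyte markers (0 up and 4 down among 22, 0 and 8 adjusted over the list alone, 0 and 1 with the set as a term, median -0.51, camera adjusted p = 4.16e-05, and adjusted p = 0.198 with an estimated correlation) down and macrophage markers (0 up and 0 down among 16, 4 and 0 adjusted over the list alone, 0 and 0 with the set as a term, median 0.75, camera adjusted p = 0.00105, and adjusted p = 0.358 with an estimated correlation) up. In the cytokine list with WD in WT, 1 rose and 0 fell among 17 tested members (3 and 0 adjusted over the list alone, 0 and 0 over all genes with the set as a term). The cytokine list had a median log2 fold change of 0.58 (camera adjusted p = 0.0103, and adjusted p = 0.132 with an estimated correlation). Il1b passed, and Cxcl9, Relb and Il1rn had adjusted p = 0.0924, 0.1503 and 0.322. In the same comparison camera called up macrophage and Kupffer cell markers (0 up and 0 down among 16, 0 and 0 adjusted over the list alone, 0 and 0 with the set as a term, median 0.52, camera adjusted p = 0.00339, and adjusted p = 0.507 with an estimated correlation) and stellate cell and matrix genes (0 up and 0 down among 15, 1 and 0 adjusted over the list alone, 0 and 0 with the set as a term, median 0.45, camera adjusted p = 0.00634, and adjusted p = 0.132 with an estimated correlation).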
